A study of Homo sapiens with 2 samples.

How the data were processed

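Single-cell RNA-seq was available for 2 libraries of Rh41, an established cell line from a human alveolar rhabdomyosarcoma. The libraries were named for CD44-negative and CD44-positive cells, so each group held 1 library and no replicate. Per the labels' protocols, RNA was captured with the 10x Genomics Chromium 3' chemistry, and staining with a CD44 antibody followed by flow cytometry was described. How the cells of each library were separated, and where a gate was set, was not given in the sources used here.

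The deposited values were whole UMI counts per gene and cell barcode, and a UMI is a tag that marks 1 captured RNA molecule. The submitters' processing notes named Cell Ranger 2.0.1, STAR and the genome build GRCh38. The annotation release was not stated. Both tables listed the same 33694 genes, of which 22210 had at least 1 UMI in either library and 19215 in both. Another gene shared its symbol in 68 cases, and these were told apart by their identifiers. A total of 73 barcode sequences occurred in both libraries, as barcodes are drawn from 1 pool. Coordinates were taken from GENCODE release 29 on GRCh38 by Ensembl identifier, and 33132 of the 33694 identifiers (98.3%) matched.

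The deposited tables held 7005 cells in the CD44-negative and 6757 cells in the CD44-positive library. Cells with at least 500 detected genes and at most 10% mitochondrially encoded UMI were kept, which left 6892 and 6670 cells and took out 113 and 87. Counts were summed over the kept cells of each library and divided by the total UMI to give CPM, the share of a gene in the library's UMI on the standard CPM scale. The log2 ratio was positive over negative library. Values in CPM carried exact Poisson 95% intervals, shares of cells carried exact (Clopper-Pearson) binomial 95% intervals, and ratios carried exact intervals from the binomial split of the UMI. All of these intervals covered counting error only.

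With 1 library per group, no test of a difference between the groups was possible, and no p-value or standard error was made from cells. Genes were counted by size alone: at least 2-fold apart and at least 20 CPM in the library where the gene was higher. The counts therefore say how these 2 libraries differed, and there was no replicate check. Gene lists were fixed from general knowledge of the tumour type, of CD44 and of cultured cells. A list was summarised by the median log2 ratio of its members with at least 5 CPM in the mean of both libraries. That median was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Lists with fewer than 5 such members were given by their values. MLF1IP of the S phase list and RGS5 of the endothelial and pericyte list had no entry under those symbols. Lists shared 13 symbols, among them CDKN1A, HES1, HEY1, HMMR and MYOD1.

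For comparisons between cells, each cell was thinned at random without replacement to 6500 UMI, and shallower cells were left out, so that 6564 and 6189 cells remained. Cell cycle phases were called with scanpy 1.11.5 from the lists of S phase and G2/M genes. Clusters were made for both libraries together with the Leiden method (igraph 0.11.9) at resolution 0.5, from 30 principal components and 15 neighbours. Of 2000 variable genes, the 1174 that lay at least 1.5-fold apart between the libraries were left out, and 826 were used. A cluster was named only when at least 3 of its 10 leading genes belonged to 1 marker list. Inside each library, thinned cells with at least 1 CD44 UMI were compared with cells without one, over genes with a mean of at least 20 CPM. That contrast was correlated across genes with the ratio between the libraries. To keep the sides independent, the contrast came from the cells at odd positions and the ratio from those at even positions. The range with CD44 status dealt at random came from 20 deals.

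For each gene with a mean of at least 0.01 UMI per cell in both libraries, Poisson, negative binomial and zero-inflated negative binomial models were fitted by maximum likelihood inside each library, with the cell total as offset. Models were compared by the Akaike information criterion (AIC), and a model was taken as better when its AIC was lower by more than 10. Dispersion, the excess of cell-to-cell variance over the Poisson, was compared between libraries over genes with a mean of at least 0.5 UMI per cell. AIC describes the fit inside a library, and cells are not replicates.

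Scrublet, as run in scanpy, called 4 and 1 cells as doublets (0.0571% and 0.0148%), too few for the loading, so doublets were kept and their removal was only an alternative. The genes named were CD44, the 15 with the largest and the 15 with the smallest log2 ratio at 20 CPM or more, up to 4 members of each list with the largest absolute ratio at 10 CPM or more, the 10 of largest dispersion per library, the 10 highest and 10 lowest in the mean CD44 contrast, and the 10 leading genes of each cluster. From these, genes were printed in order of size, and any other gene is marked as chosen after its values were seen.

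The ratio between libraries, the count models, the CD44 contrast and the medians along chromosomes were tested on simulated data. The list percentile was tested with random lists drawn from the measured ratios. Clustering, phase calls and the overlap of gene models had no such test. The ratio between libraries was run on 4352 simulated genes, where all 200 changed genes passed 1.5-fold and 0 of 4152 unchanged genes did. That simulation held counting error only, so it says nothing about variation between library preparations. Of 200 random lists of 20 genes, 14 (7%) fell outside the central 95%, and a list raised 1.5-fold reached percentile 100. Among 2000 simulated genes per library, 0 of 1600 negative binomial genes were called zero-inflated and 0 of 200 Poisson genes were called negative binomial. Of the zero-inflated genes with a mean of at least 0.5 UMI, 41 of 50 and 45 of 55 were recovered in the settings of the negative and positive library, but only 42 and 47 of all 200, so added zeros were seldom found at lower means. The simulated CD44 contrast (4514 genes) returned median folds of 1.48, 1.99 and 4.01 for true folds of 1.5, 2 and 4. For medians along chromosomes (3784 genes), a 1.5-fold shift of 27 of 274 windows raised the SD from 0.121 to 0.213, above the highest of 100 shuffles at 0.138.

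The alternatives covered the cell filter, called doublets, scaling by a median ratio or by TMM factors from edgeR 4.0.16 under R 4.3.3, weighting each cell alike, totals without mitochondrial and ribosomal genes, depth, the filter on low counts, the fold threshold, the summary of a list, cluster resolution, variable genes, the AIC gap, the offset and the CD44 threshold. A set without the 5% of cells with most UMI, and a set with only the cells of 4 clusters, were chosen after seeing the data. Computing used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. Reads were not used here, and sequence variants and splice forms of CD44 were not analysed here.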

Results

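Rh41 is a cell line grown from an alveolar rhabdomyosarcoma, a childhood tumour whose cells carry parts of the skeletal muscle programme. Transcriptomes of single cells were collected from 1 library named CD44 negative and 1 library named CD44 positive, after CD44, a surface receptor for the matrix sugar hyaluronan. The deposited tables held 7005 and 6757 cells. The kept cells of the CD44-negative library held 115072389 UMI in 6892 cells, with a median of 15184 UMI and 3152.5 genes per cell. Those of the CD44-positive library held 83932548 UMI in 6670 cells, with a median of 11483.5 UMI and 2817 genes. Mitochondrially encoded genes took 4.87% and 4.83% of UMI, and ribosomal protein genes took 39.9% and 37.1%. Each group had 1 library, so every difference below lacks a replicate check, and all intervals cover counting error only.

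The first comparison asked whether CD44 RNA followed the names of the libraries. CD44 (ENSG00000026508, GRCh38 chromosome 11, 35138870 to 35232402) was nearly absent from the CD44-negative library and clearly present in the other. It stood at 0.791 CPM (its share of the library's UMI on the standard CPM scale, 95% Poisson interval 0.637 to 0.971, 91 UMI) in the negative library. In the positive library it stood at 43.0 (41.6 to 44.4, 3606 UMI), 54.3-fold higher (44.1 to 67.7). CD44 UMI were seen in 84 of 6892 negative cells (1.22%, exact binomial interval 0.973 to 1.51) and in 2306 of 6670 positive cells (34.6%, 33.4 to 35.7). The positive cells had the lower median depth, 11483.5 against 15184 UMI. After all cells were thinned to 6500 UMI, the shares were 0.609% and 22.6%. Free RNA in the positive library comes from its own cells, so the shares carry no background value. A positive cell without a CD44 UMI need not lack the transcript, as the mean was 0.541 CD44 UMI per cell.

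The next comparison asked which other genes differed between the libraries. LRRC17, a secreted leucine-rich repeat protein, went from 0.652 CPM in the negative to 50.1 in the positive library (76.8-fold, 61.1 to 97.8). DKK1, a secreted WNT inhibitor, went from 0.417 to 30.9 (74.2-fold). ANXA1, a calcium-dependent membrane binder, went from 1.36 to 92.7 (68.3-fold). NNMT, which methylates nicotinamide, was 56.2-fold higher and CTGF, a matrix protein induced by YAP, 54.4-fold. The secreted glycoprotein LGALS3BP was 29.2-fold higher, ISG15, a ubiquitin-like interferon product, 19.3-fold, and TAGLN, an actin binder of smooth muscle, 19.2-fold. The calcium binder S100A16 was 16.3-fold higher, the matrix protein CYR61 15.6-fold, the kinase PLK2 14.3-fold, the growth factor binder IGFBP6 14.2-fold and LMO7 9.48-fold. For IFI44, another interferon product, the log2 ratio was 4.07.

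Changes in the other direction were smaller. MYOG, the factor that starts muscle differentiation (chromosome 1, 203083132 to 203086036), stood at 350 CPM in the negative and 119 in the positive library, 2.94-fold lower (2.88 to 3.01). The sialidase NEU4 was 4.30-fold lower and the sulfotransferase CHST8 3.81-fold. PKDCC, a secreted kinase, was 2.94-fold lower, the meiotic gene SYCE1 2.90-fold, C1orf105 2.85-fold and DCX, a microtubule protein of migrating neurons, 2.77-fold. The transcription factor TFAP2B was 2.73-fold and GADD45G 2.71-fold lower. VGLL2, a TEAD cofactor of muscle, had a log2 ratio of -1.32, and TTN, the giant spring of the sarcomere, was 2.44-fold and MYBPHL 2.38-fold lower. ERVW-1, the envelope gene of an endogenous retrovirus, was 2.76-fold lower, and its reads can be shared with near-identical retroviral copies. ERVW-1 also led cluster 3 (below), at 221 CPM against 21.5 in the other cells. TTN was highest in that cluster as well, at 173 CPM against 112 in cluster 0. Cluster 3 held 43.8% of negative and 9.94% of positive cells, so unequal cluster shares enter both ratios. Among 4624 genes at 20 CPM or more, 189 (4.09%) were at least 2-fold higher in the positive library, 33 (0.714%) at least 2-fold lower, and 4402 lay within 2-fold. The median log2 ratio of these genes was 0.0446, and the Pearson correlation of log2 levels across genes, which are not independent replicates, was 0.963.

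**Figure D1:**
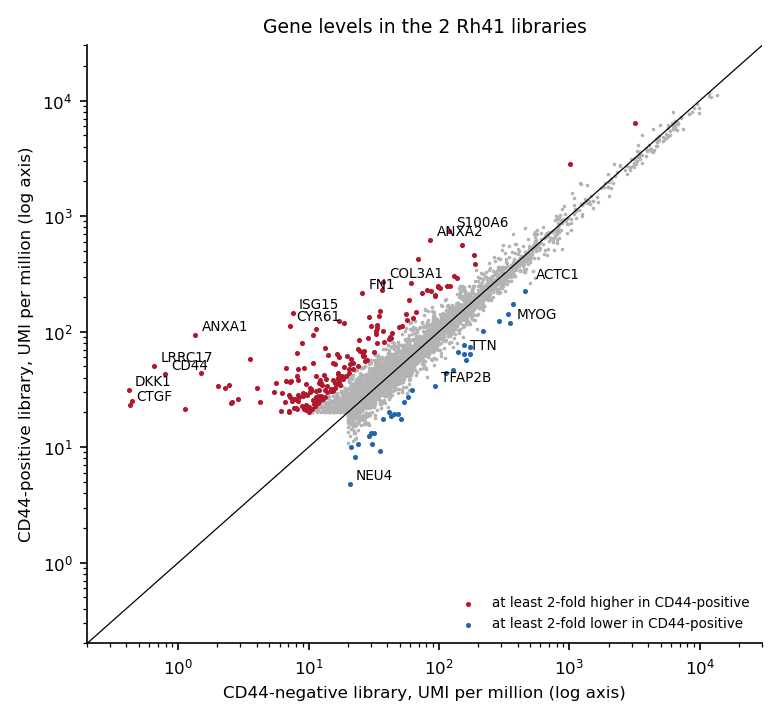
Each point is 1 gene, placed by its CPM in the CD44-negative (x) and CD44-positive (y) library on log axes, for genes with at least 20 CPM in either library. Red points are at least 2-fold higher and blue points at least 2-fold lower in the CD44-positive library. The red points reach far from the diagonal at low levels of the negative library (CD44, LRRC17, DKK1), while the blue ones stay within 4.30-fold.

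Gene lists placed these genes in groups. The list of mesenchymal and matrix genes lay far above 0, with 23 of 24 measured members above 0 and a median log2 ratio of 1.40 (percentile 100 of random lists). Besides ANXA1 and TAGLN it held S100A4, a calcium binder of motile cells (28.1-fold higher), and COL1A1, the main chain of type I collagen (24.5-fold). All 10 YAP and TEAD targets lay above 0 (median 0.99, percentile 100), led by the receptor kinase AXL, which went from 0.130 to 14.6 CPM. Of 12 WNT and Notch genes, 10 lay above 0 (median 1.02, percentile 100), among them the Notch ligand JAG1 (25.2-fold) and the Notch targets HEY1 (5.80-fold) and HES1 (3.40-fold). All 9 interferon response genes lay above 0 (median 0.89), with IFI6 4.72-fold and B2M, the light chain of MHC class I, 2.46-fold higher. The list of unfolded protein and amino acid response genes had a median of 0.43 (percentile 100), and PDIA4, which folds proteins in the endoplasmic reticulum, was 1.95-fold higher.

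Lists tied to the muscle tumour lay on the other side. The muscle differentiation list had 12 of 14 measured members below 0 and a median of -0.40 (percentile 0). MYLPF, a light chain of fast myosin, was 2.03-fold lower, and ACTC1, the cardiac actin, 1.89-fold, as was CHRND, a subunit of the muscle acetylcholine receptor. The list of genes associated with PAX3-FOXO1, the fusion factor found in most alveolar rhabdomyosarcomas, had 15 of 19 members below 0 and a median of -0.45 (percentile 0). Its median was -0.25 with totals without mitochondrial and ribosomal genes and -0.19 without the filter on low counts. Besides TFAP2B, it held MYCN and ASS1, an enzyme of arginine synthesis, both 1.70-fold lower. Myogenic factors went both ways, with 9 above and 8 below 0, a median of 0.16 (percentile 87.2) and a mean of -0.12 (percentile 0.70 of random means), so no direction is read for this list. MSC, a repressor of myogenic factors, was 2.51-fold higher, whereas RASSF4 had a log2 ratio of -0.97. Ribosomal protein genes had 67 of 82 members below 0 (median -0.11, percentile 0.35). RPS10 was the lowest of them, 1.88-fold lower, and 39.4% of its exon length is shared with another gene model, so its UMI are uncertain.

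Lists of proliferation were split. S phase genes had 36 of 40 members below 0 (median -0.17, percentile 0), with GINS2, part of the replicative helicase, 1.46-fold lower. G2/M genes had 42 of 53 members above 0 (median 0.21, percentile 99.98), with the cytokinesis scaffold ANLN 1.88-fold higher. The CDK inhibitor and quiescence list had a median of 0.22 (percentile 95.7). CDKN1A, an inhibitor of cyclin-dependent kinases, was 2.92-fold higher and CDKN2C 1.89-fold higher, while CCND2, a cyclin of the G1 phase, was 2.35-fold lower. Scores per cell called 33.6% (32.4 to 34.7) of thinned negative cells and 24.8% (23.8 to 25.9) of thinned positive cells as S phase. The shares called G2/M were 64.6% and 67.3%, and those called G1 were 1.86% and 7.88%. Each call follows the leading score, and at library level the G2/M score led: 0.201 against 0.0791 (negative) and 0.224 against 0.0284 (positive). The shares therefore do not measure the fraction of cells in each phase. Among the clusters given below, only clusters 4 and 6 had all 15 G2/M markers raised at least 1.5-fold. They held 15.9% and 0.229% of negative and 15.8% and 10.1% of positive cells. Free RNA also enters the phase calls and stays open here, and no difference in cycling is read from them.

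The medians of the remaining lists lay between -0.02 and 0.31. Cholesterol synthesis genes had 15 of 17 members above 0 (median 0.26, percentile 98.7), with MVK 1.40-fold higher. CD44 partners and hyaluronan genes had a median of 0.31 (percentile 97.2), with VCAN, a proteoglycan that binds hyaluronan, 2.96-fold and the surface protease MMP14 3.16-fold higher. Markers of stem and tumour-initiating cells had a median of 0.18 (percentile 82.2; 0.00 and 15.8 for 21 members without the filter on low counts), and within that list the receptor NOTCH3 was 2.81-fold higher and MYC 1.54-fold lower. The hypoxia list had a median of 0.22 (percentile 84.9), with LOX, which crosslinks collagen, at 0.0782 against 11.5 CPM. The median was 0.18 for TGF-beta and BMP response (percentile 80.6), 0.15 for NF-kB and cytokine genes (percentile 63.1), 0.14 for immediate early and heat shock genes (percentile 79.0) and 0.11 for p53 targets (percentile 58.7). JUN, an AP-1 factor, was 2.59-fold higher, and GDF15, a stress cytokine of the p53 list, 2.34-fold. The respiratory chain list had a median of 0.06 (percentile 99.2). The median was 0.00 for replication-dependent histones (percentile 28.6), -0.01 for glycolysis (percentile 42.7, mean 0.08) and -0.02 for mitochondrially encoded genes (percentile 55.1, mean 0.01).

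Lists of other cell types were hardly measured. Of the neuronal list, 3 genes passed the filter, with the adhesion molecule L1CAM 5.70-fold and the vesicle protein SYT1 2.56-fold higher and DCX lower, as given above. Of the endothelial and pericyte list only EGFL7 passed, 1.23-fold higher. The lists of immune, epithelial, and erythroid and adipocyte markers had 0 measured members. Without the filter on low counts, the medians were 2.49 for 7 epithelial markers (percentile 99.96), 1.59 for 9 endothelial and pericyte markers (99.9), 1.04 for 9 immune markers (96.8) and 0.91 for 10 neuronal genes (99.6), and only the immune list lay inside the central 95% of random lists. The signs of the respiratory chain, p53, glycolysis, hypoxia and histone medians changed under at least 1 other scaling, so no direction is read for them. With the mean in place of the median, the lists of G2/M genes (percentile 94.7), unfolded protein and amino acid response (94.9), cholesterol synthesis (91.8) and respiratory chain (86.9) lay inside the central 95% of random lists. The same setting placed hypoxia (99.8), CD44 partners and hyaluronan genes (98.4) and stem cell markers (97.6) above it, and myogenic factors below it. The TGF-beta and BMP list lay above it in thinned cells (98.4), with each cell weighted alike (98.3) and with totals without mitochondrial and ribosomal genes (98.1). It also did so without the 5% of cells with most UMI (98) and with only clusters 0, 1, 3 and 4 (99.6). Without the filter on low counts, its median was 0.68 for 21 members (99.99). In the remaining settings it lay inside.

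**Figure D2:**
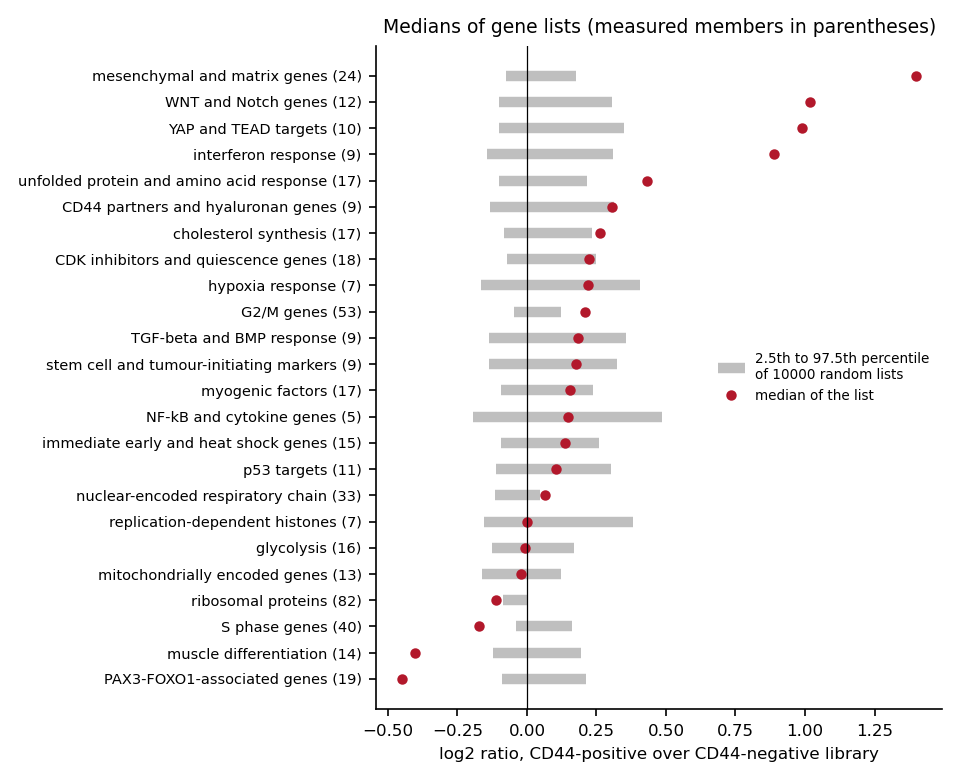
Red points show the median log2 ratio (x, CD44-positive over CD44-negative library) of each gene list (y, number of measured members in parentheses), and grey bars span the central 95% of 10000 random lists matched on expression. Mesenchymal and matrix genes lie farthest right at 1.40 and PAX3-FOXO1-associated genes farthest left at -0.45.

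Clustering asked whether the difference ran through all cells or came from a part of them. The positive library held a large cluster of mesenchymal-like cells that was almost missing from the negative library. This cluster 2, led by CTGF, DKK1, LRRC17 and CYR61 with ANXA1 among its 10 leading genes, held 37.5% (36.3 to 38.7) of positive and 1.55% (1.27 to 1.88) of negative cells. Cluster 6, led by ANXA1, S100A16 and DEPDC1 and not named, held 10.1% and 0.229%. Cluster 3, led by ERVW-1, MPRIP, SLC29A1 and CENPV and with CCND2 among its 10 leading genes, held 43.8% (42.5 to 45.0) of negative and 9.94% (9.20 to 10.7) of positive cells. Cluster 0, led by the muscle genes MYLPF and MYL4 with VGLL2, held 18.2% and 6.85%. Cluster 4, led by mitotic genes such as PLK1, AURKA, CCNB1 and CDC20, held 15.9% and 15.8%. Cluster 1, with HEBP2 and HIST1H4C among its leading genes, held 20.2% and 19.8%, and cluster 5 held only 8 cells. To match the shares of both libraries, 45.8% of cells would have to change cluster, and a cluster that follows a library cannot be told from an effect of the library itself.

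Cells in clusters 2 and 6 made up 47.6% of the positive library and 1.78% (117 cells) of the negative library. These 2 clusters were grouped after the clusters were seen, as those with most CD44, so more CD44 in them follows from the choice. Within the positive library, CD44 stood at 72.8 CPM (69.0 to 76.7) in these clusters and at 21.4 (19.4 to 23.4) in clusters 0, 1, 3 and 4. In the same 4 clusters of the negative library it stood at 0.908 (0.642 to 1.25). MYOG showed the reverse, with 22.1 CPM in clusters 2 and 6 of the positive library, 189 in its other cells and 359 in the other cells of the negative library. Between the 2 parts of the positive library, 208 of 4813 genes were at least 2-fold higher and 77 lower in clusters 2 and 6. Between the other cells of both libraries, 75 of 4459 genes were at least 2-fold higher and 3 lower in the positive library. Of these, 67 of the 75 and all 3 were also at least 2-fold apart between the whole libraries. Cluster make-up enters this contrast, as cluster 3 held 2872 of these 6441 negative but 615 of these 3242 positive cells. All 189 genes higher in the whole positive library lay above 0 in that last comparison, and all 33 lower genes lay below 0. The calls came from all cells, those of this comparison included, so the shared signs are largely built in. Between the other cells of both libraries, mesenchymal and matrix genes kept a median of 0.92 (percentile 100) and muscle differentiation genes one of -0.31 (percentile 0). Markers of stem and tumour-initiating cells had a median of 0.63 there (percentile 100). The medians of PAX3-FOXO1-associated genes (-0.08, percentile 6.14), YAP and TEAD targets (0.25, percentile 92.5), unfolded protein and amino acid response (0.12, percentile 97.3), cholesterol synthesis (0.02, percentile 50.3) and ribosomal protein genes (-0.03, percentile 50.6) lay inside the central 95% of random lists there.

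**Figure D3:**
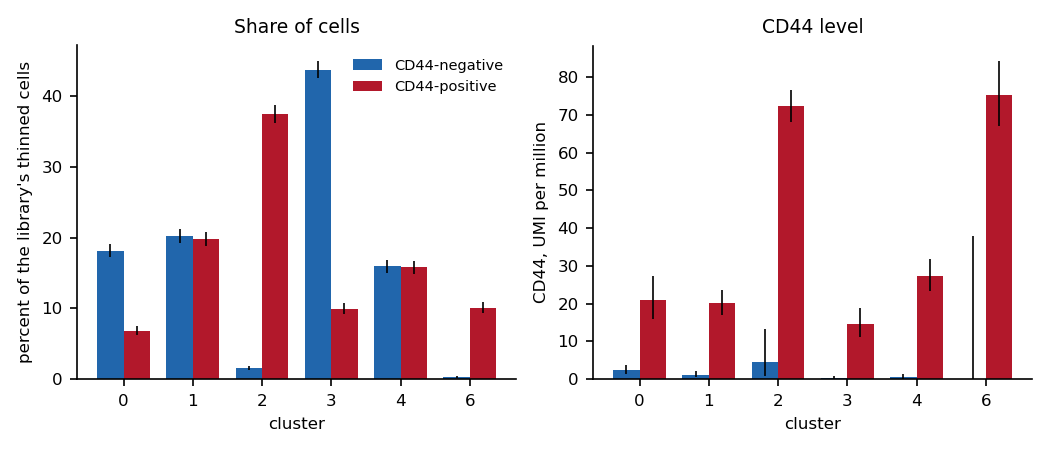
Bars give, for clusters of at least 100 cells, the share of each library's thinned cells (left, percent, exact binomial 95% intervals) and the CD44 level (right, CPM, exact Poisson 95% intervals) in the CD44-negative (blue) and CD44-positive (red) library. Clusters 2 and 6 are made up almost wholly of cells of the positive library, and every cluster shown has more CD44 in the positive library.

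A contrast inside 1 library cannot carry a difference between library preparations, so cells with and without CD44 UMI were compared within each. Inside the positive library, cells with CD44 had more of the genes that set that library apart and fewer muscle transcripts. The log2 ratio was 1.01 for ANXA1, 1.03 for LRRC17, 1.02 for LGALS3BP, 1.05 for CYR61 and 0.93 for the matrix protein FN1. It was 0.81 for the Notch target HES4, 0.63 for ANXA2 and -1.43 for MYLPF, which stood at -0.77 without thinning and at -2.59 when at least 2 CD44 UMI were asked for. Mesenchymal and matrix genes had a median of 0.48 and interferon response genes one of 0.51, while muscle differentiation genes had one of -0.52 and PAX3-FOXO1-associated genes one of -0.33. The contrast set 1400 cells against 4789. Across 4373 genes it correlated with the ratio between the libraries (Pearson 0.703, Spearman 0.633), and CD44 status dealt at random gave Pearson values from -0.16 to 0.13. All 137 measured genes at least 2-fold higher between the libraries, and all 29 lower ones, had the same sign inside the positive library, against 60.2% and 38.2% of the other genes. The calls came from all cells, those of this contrast included. CD44 UMI were seen in 34.4% of thinned positive cells of clusters 2 and 6 and in 11.9% of those of clusters 0, 1, 3 and 4. The contrast therefore also carries the difference between these clusters, and none was made inside a single cluster.

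Inside the negative library, only 40 cells with CD44 UMI stood against 6524. There the Pearson correlation with the ratio between the libraries was 0.216 (Spearman 0.190), and that between the contrasts inside both libraries was 0.189 (0.180). Of the higher genes 110 of 137, and of the lower ones 24 of 29, had the same sign, against 42.3% and 56.4% of the other genes. ANXA1 (log2 ratio 3.64) and LRRC17 (2.87) rested on 4 and 1 UMI in the cells with CD44, and FN1 (2.04) on 31. For 45 G2/M genes the median was -0.51 (percentile 0) in the negative and -0.03 (percentile 0.70) in the positive library. Both are opposite in sign to the 0.21 of that list between the libraries.

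**Figure D4:**
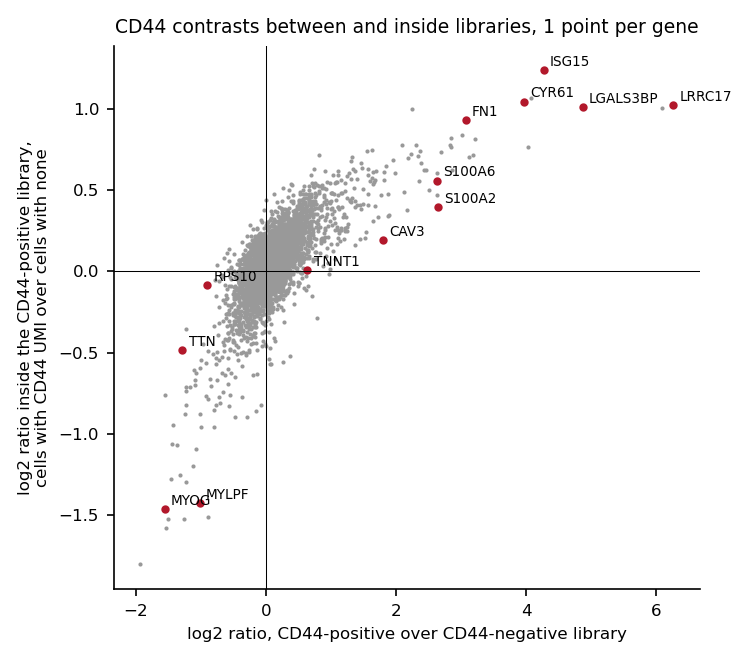
Each point is 1 of 4373 genes, with the log2 ratio between the libraries on x and the log2 ratio of cells with over cells without CD44 UMI inside the CD44-positive library on y. Genes such as LRRC17 and CYR61 lie at the upper right and MYLPF and MYOG at the lower left.

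The series title named the modelling of UMI counts, so the spread of counts between cells was described for each gene. Dispersions were ranked only among genes with a mean of at least 0.5 UMI per cell in both libraries. TMSB4X, an actin-binding peptide, had the largest dispersion of the negative library (7.16, against 4.32 in the positive), followed by the keratin KRT17 (4.26) and by S100A10 (3.46). ERVW-1 had the largest of the positive library (5.40, against 1.94 in the negative). MYOG had a dispersion of 0.273 in the negative and 2.48 in the positive library, and TTN had 0.782 and 2.04, so these muscle genes, lower in the positive library, were also more uneven among its cells. The slow troponin TNNI1 was uneven in both, at 2.32 and 2.70.

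Of 11823 genes, 4410 (37.3%) in the negative and 4242 (35.9%) in the positive library were better fitted by the negative binomial than by the Poisson. At a mean of 0.5 UMI per cell or more, the shares were 90.7% and 87.8% of 2659 genes. A model with added zeros improved on the negative binomial for 24 genes (0.203%) in the negative and 59 (0.499%) in the positive library. In the positive library these included ASS1, MYOG, S100A10 and ANXA1. Many others were mitochondrially encoded or ribosomal protein genes with very few zeros, such as MT-CO2 (0.165% of cells) and RPS6 (0.105%). CD44 passed narrowly (AIC difference -11.9). Its share of cells without a UMI, 65.4%, was not above the 66.0% that the negative binomial gave. More than 1 percentage point of excess zeros was left in 2780 and 2488 genes by the Poisson and in 399 and 97 genes by the negative binomial. The last 2 counts were 0 and 5 in thinned cells and 0 and 7 without an offset, so they hang on depth and the offset. The AIC counts depend on depth, as 1963 and 2360 genes were better fitted by the negative binomial after thinning.

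Dispersion was similar in rank but somewhat larger in the positive library. Its median was 0.0973 in the negative and 0.113 in the positive library, the median log2 ratio was 0.21, and 222 genes were at least 2-fold higher in the positive library against 61 lower. The split was less uneven in thinned cells (404 against 224) and at a mean of 0.1 UMI per cell or more (1248 against 764). Across 2659 genes the correlation between libraries was 0.698 (Pearson, log2 values) and 0.835 (Spearman). After thinning these were 0.364 and 0.673. Some fitted dispersions lay at the lower limit of the fit in 1 library. Examples are UFC1 (0.106 in the negative, 6.18e-06 in the positive library) and TFPT (6.18e-06 and 0.0613). Such fits weigh on the Pearson value of log2 dispersions and enter the counts of 2-fold differences, and how far was not tested.

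**Figure D5:**
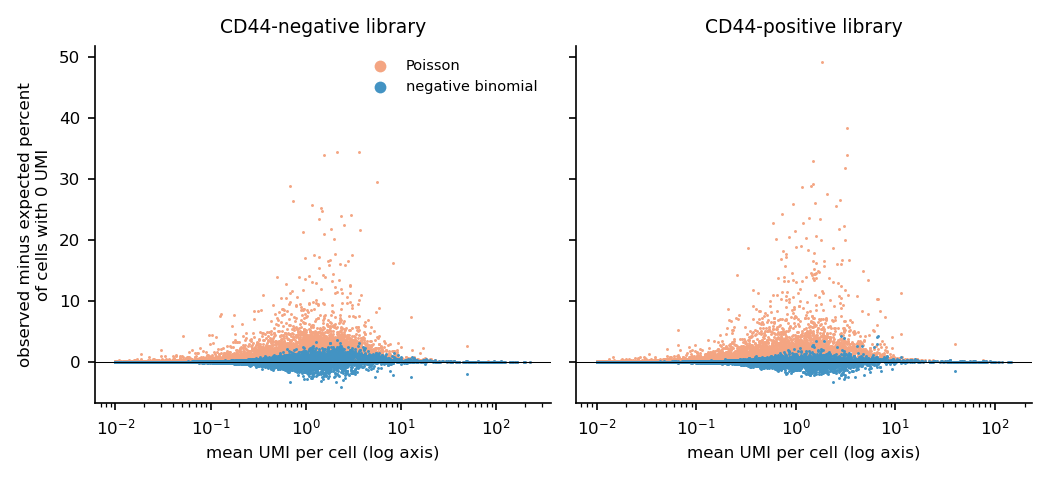
Each gene is shown once per model, with its mean UMI per cell on x (log axis) and the observed minus expected percent of cells without a UMI on y, for the CD44-negative (left) and CD44-positive (right) library. Under the Poisson (orange) the excess rises with the mean for many genes, and under the negative binomial (blue) it stays at or under 4.22 points.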

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

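The comparison of list medians between the 2 CD44 contrasts was chosen only after the results were seen, and no explanation was weighed for it. For 5 gene lists the median log2 ratio of cells with over cells without CD44 UMI had opposite signs inside the libraries, and none of these differences was tested. Cholesterol synthesis genes had -0.0333 in the negative and 0.216 in the positive library (13 members). Glycolysis genes had -0.0570 and 0.00334 (11 members), and nuclear-encoded respiratory chain genes -0.0352 and 0.0496 (33 members). Immediate early and heat shock genes had 0.390 and -0.0347 (8 members), and mitochondrially encoded genes -0.212 and 0.00463 (12 members). The contrast inside the negative library rested on 40 cells with CD44 UMI, so its medians are imprecise.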

How the results depend on the processing

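The alternatives were set before the data were examined, except 2 chosen after seeing the data (without the 5% of cells with most UMI, and only the cells of clusters 0, 1, 3 and 4, thinned). No paired analysis was possible because each group held 1 library. The cause was not tested except where the setting itself gives it, as a lower fold or count limit admits more genes and a higher one fewer. CD44 had a log2 ratio of 4.56 with only clusters 0, 1, 3 and 4, and that setting gave 75 higher and 3 lower genes and 2 lists below the range of random lists. The higher and lower genes numbered 489 and 68 at 5 CPM or more, 44 and 14 at 100 or more, and 436 and 102 at 1.5-fold. Totals without mitochondrial and ribosomal genes gave 259 higher genes with 166 of the 189, and 54 lower genes with all 33, and under TMM scaling 147 higher genes, all among the 189, and 47 lower genes were counted. TMM moved the median log2 ratio of all genes from 0.0446 to -0.0730. Among named genes, 2 histone genes changed sign: HIST1H1E with only clusters 0, 1, 3 and 4 (0.038) and HIST1H4C under TMM scaling (-0.041). Both lay past their counting interval at the start, whereas HIST2H2AC, which changed sign as well, started inside it (0.00). The medians of 8 of 24 lists changed sign in at least 1 setting, and of these only the respiratory chain had a main value outside the random range: myogenic factors (mean -0.12), p53 targets, immediate early and heat shock genes, hypoxia, glycolysis, respiratory chain, histones and mitochondrially encoded genes. Cluster shares differed by 44.4% of cells at resolution 0.25, 55.8% at resolution 1.0 and 57.6% with all variable genes.

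The negative binomial was better than the Poisson for 6727 genes of the negative library without an offset, and for 1963 (negative) and 2360 (positive) in thinned cells. Added zeros helped 143 and 164 genes at an AIC gap of 2. In the positive library they helped 31 genes without an offset and 35 in thinned cells. For dispersion, the Pearson correlation was 0.270 and the Spearman 0.637 at a mean of 0.1 UMI per cell or more, and 0.364 and 0.673 in thinned cells. The correlations of the CD44 contrast (positive with between, negative with between, negative with positive) were 0.624, 0.263 and 0.149 at 2 CD44 UMI or more (2 negative cells). They were 0.781, 0.482 and 0.372 without thinning, where depth enters, and 0.779, 0.394 and 0.315 at a mean of 100 CPM. Without thinning the CD44 contrast of AURKA inside the positive library changed sign (0.0273), and at 2 CD44 UMI or more NOL8 did so from a value near 0 (-0.0824), out of 20 genes. Of the values for the main results, 69 stayed and 34 moved. None reversed, but most were counts or shares that could not reverse, so this says little about direction.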

Other observations

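The tests of library preparation, of non-muscle cells, of free RNA, of CD44-negative cells in the positive library, of chromosome blocks, of a single library and of genes without a shared exon were chosen only after the results were seen, whereas those of depth and of the share with an overlapping gene model were set beforehand. The genes named in this part were chosen after their values were seen, unless the report names them.

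The cells of clusters 2 and 6 differed from the other cells of the positive library in more than matrix genes. All 17 cholesterol synthesis genes lay above 0 between these parts (median log2 ratio 0.54, percentile 100), as did all 9 interferon response genes (0.86, percentile 100), and unfolded protein and amino acid response genes had a median of 0.59. Myogenic factors had a median of -0.30 and G2/M genes one of -0.12, each at percentile 0. The G2/M value pools 2 unlike clusters, since 15 G2/M markers, over all other cells of both libraries, had a median of -1.01 in cluster 2 and of 1.44 in cluster 6, whose leading genes include PIF1 and CDC20. PALMD was 22.5-fold, the long noncoding RNA SFTA1P 13.5-fold and the axon guidance factor SEMA3A 10.7-fold higher in clusters 2 and 6. ARHGAP8 was 15.9-fold lower there, SNAI1, a transcription factor of epithelial to mesenchymal transition, 5.59-fold and the neurotrophin receptor NGFR 4.39-fold.

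The 117 negative cells in clusters 2 and 6 had a partly different profile from the positive ones. Against the other negative cells they had 17.9-fold more STATH and 8.68-fold more MGP, an inhibitor of calcification, while STATH was level between the parts of the positive library (0.974-fold). FN1 was 6.34-fold and ISG15 8.49-fold higher in them, and MYOG 2.68-fold lower. They held 3 CD44 UMI, or 3.94 CPM (0.814 to 11.5).

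The genes at least 2-fold apart between the libraries were weighed first. A difference in library preparation or sequencing run would leave the CD44 contrast inside the positive library unrelated to the ratio between libraries, and the correlation was 0.703, against at most 0.13 with CD44 dealt at random, so it is not the whole cause. After thinning to equal depth the count of higher genes was 202, against 189. Random thinning keeps the expected share of a gene in each cell's UMI. It only weights cells alike and leaves out the shallowest, so this count cannot decide on unequal depth, which stays open. Non-muscle cells of another origin would lack myogenic factors, but 7 of 9 kept at least 25% of their level in clusters 2 and 6, with CDH15 at 156%, DES at 105% and MYOD1 at 49.4%, whereas VGLL2 kept 14.2% and MYOG 6.15%. These values are consistent with a hypothesis of a less differentiated, mesenchymal-like state of the tumour cells that goes with CD44, but a small share of other cells and a difference in copy number (below) stay open, and 1 library per group cannot generalise.

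CD44 UMI in positive cells outside clusters 2 and 6 were weighed next. Free RNA from clusters 2 and 6 would keep 1 ratio of CD44 to ANXA1 UMI, and the ratio was 1.24 (1.08 to 1.43) outside against 0.395 (0.371 to 0.420) inside. Free RNA apart, had all these cells been CD44-negative cells that entered the positive library, CD44 would have stood at 0.908 CPM there (0.642 to 1.25), and it stood at 21.4 (19.4 to 23.4). A fraction of such cells stays open. The values suggest that CD44-positive cells include muscle-like ones, as a hypothesis.

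Cluster 3 was weighed last, since its leading genes MPRIP, CENPV, DRG2 and COPS3 lie together on chromosome 17 (GRCh38, 16342534 to 18107971), CD9 and CCND2 on chromosome 12 and NQO2 at the start of chromosome 6. Over 3784 other genes not used for clustering, medians of the contrast of cluster 3 with clusters 0, 1 and 4 in windows of 5000000 bases spread with an SD of 0.237 in the negative and 0.219 in the positive library, against at most 0.143 and 0.140 in 1000 shuffles. The median log2 ratio was 0.74 and 0.80 at 15000001 to 20000000 on chromosome 17, 0.72 and 0.74 over the first 5000000 bases of chromosome 12, and -0.53 and -0.41 at 55000001 to 60000000 there, while 148 and 145 of 162 genes on chromosome 9 lay above 0. The window medians correlated at 0.922 between libraries, so the blocks were not confined to 1 library. Both libraries were clustered together, which groups cells alike in expression and can raise this correlation. The cluster 3 medians of the negative library correlated at only 0.146 with those of deep over shallow cells. That argues against depth, although cluster 3 had the highest median depth of the clusters (19999 UMI). Clusters 2 and 6 of the positive library, set against clusters 0, 1 and 4, also had an SD (0.180) above their highest shuffle (0.162) and correlated with cluster 3 at 0.477. The 3 windows just named stood at 0.22, 0.18 and 0.07 there, near the 0.13 of all genes. Other windows lay low in both contrasts. Both were set against clusters 0, 1 and 4, so a block particular to those cells would enter both and raise their correlation. Cluster 3 was not compared directly with clusters 2 and 6. At 230000001 to 235000000 on chromosome 1, cluster 3 had -0.54 and -0.49, and clusters 2 and 6 had -0.47. At 30000001 to 35000000 on chromosome 13 these were -0.54, -0.48 and -0.36. The pattern is consistent with a subclone, or cells of a related line, that differs in chromosome copy number and made up more of the negative library, but DNA was not measured in the data used here.

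Reads shared with an overlapping gene model were tested for the 37 genes that lay at least 1.5-fold apart between libraries with at most 0.15 of that ratio inside the positive library. The share with at least 50% of the exon length inside another model on the same strand was 2.70% (0.0684 to 14.2) against 0.732% of all genes, which leaves the share test undecided. No exon base was shared in 31 of the 37 genes (83.8%, 68.0 to 93.8), so this source does not account for the set. For the 6 others, RPS10 among them, it stays open. The unequal share of cluster 3 in the libraries was not weighed for this set and stays open as well. The set includes CD9, a leading gene of cluster 3, and GID4, which lies in the chromosome 17 window given above. Both were lower in the positive library.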
